A study of Mus musculus with 4 samples.

How the data were processed

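Gastrocnemius muscle of mice was profiled on Affymetrix arrays, with 1 array for each of 4 groups. The groups were wild-type (WT) mice given vehicle, WT mice given streptozotocin (STZ), and mice lacking the transcription factor KLF15 in skeletal muscle only (KO) given vehicle or STZ. STZ destroys the insulin-producing beta cells of the pancreas and is used to make mice diabetic. Per the labels' protocols, STZ was injected intraperitoneally at 50 mg/kg on 5 days in a row, in 50 mM citrate at pH 4.5, and muscle was taken 3 weeks after treatment. Per the labels' protocols, total RNA was purified on silica columns and 4 ug of it was turned into biotin-labelled cRNA.

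The deposited table holds 1 linear intensity value per transcript cluster and array, for 41345 clusters. The background correction, summary method and normalization that the authors used are not given in the sources used here. The sorted log2 values of the 4 arrays departed from their mean by at most 0.17. The arrays were close at the median but less so at the bright end. There, percentile 95 of intensity ran from 179.4 in KO STZ to 206.8 in WT STZ. Whether and how the values were scaled between arrays is not given in the sources used here. No detection calls or scan dates were used. The number of arrays limits the precision, and no error between animals can be given.

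Intensities were turned into log2(intensity + 3.69), where the offset is percentile 25 of all values. The log2 medians of the arrays lay within 0.035 of each other, inside the limit of 0.1 set beforehand, so no further scaling was applied. Differences on this scale understate the change of dim genes. Of the clusters, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed in the annotation. Of those with 1 symbol, 23328 were matched to a RefSeq gene table through their Entrez number and 0 symbols changed. A gene was represented by its brightest cluster. Of 22180 genes, 13258 had a mean log2 value above the median of all clusters, which corresponds to an intensity of 5.81, and were kept. Genomic positions are not reported because no genome build is named.

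The comparisons were STZ against vehicle in each genotype, KO against WT under each treatment, and the difference between the STZ effects of the genotypes. With 1 array per group no test was run, and no p-value or standard error was made. An additive model of genotype and STZ would leave 1 residual degree of freedom but was not used, because its residual is the very difference between STZ effects that the design asks about. Genes were counted at 2-fold or more (1 on the log2 scale). The comparisons within WT and within KO share no array, and neither do the KO comparisons under vehicle and under STZ.

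Before the data were examined, 35 gene lists were fixed, 21 of pathways and 14 of cell type or sex markers. They held 544 distinct genes, of which 501 were matched and 464 passed the level filter. Some genes belong to several lists, such as Cebpd and Ddit4 in the atrophy and glucocorticoid-responsive lists, so the calls of lists are not independent. For each of the 28 lists with at least 5 measured genes, the median log2 difference was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean level. A list is called apart at or below percentile 2.5 or at or above percentile 97.5, as a description of these arrays. If the members of a list varied independently, 5% of lists would be called by chance, and co-expressed members can raise that share. Because the matched genes of an array can share a shift, a list can be apart with a median near 0. The draws were repeated with other random seeds, to 6 draws in all, after the first percentiles had been seen.

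The genes named were fixed in advance by rule. They are Klf15, the 12 largest differences each way in each pairwise comparison and the 10 largest for the difference between STZ effects, up to 4 members per list, and 9 genes of interest. Genes changed at least 2-fold the same way by STZ in both genotypes were also named. Any gene named outside the rule is marked as such.

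The counting and the list percentiles were tested on simulated data, in which measured differences were shuffled among genes of like level. For WT STZ against WT vehicle, with 13258 genes, 99 of 100 genes changed by 1.5 on the log2 scale were counted past 2-fold, and 16 of 100 changed by 0.8. In the same comparison 27 of 28 lists shifted by 0.3 were called apart. For KO against WT under vehicle, 97 of 100 genes changed by 1.5 were counted. The changes were added to finished log2 differences, so these counts follow from the spread of the differences. They do not show how the offset damps changes of dim genes. Because shuffling makes genes of like level exchangeable, as the random lists assume, the rate of calls among unshifted lists follows from construction and gives no error rate for lists of co-expressed genes.

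Alternatives were quantile normalization, removal of a loess trend with level (span 0.3), no level filter or one at percentile 75, the mean of all clusters of a gene, a floor or nothing in place of the offset, and a 1.5-fold threshold. A count of protein-coding genes without chemosensory receptor genes, and a filter above percentile 95 of those receptor genes, were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.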

Results

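Transcript levels were measured in gastrocnemius, a calf muscle made mostly of fast fibres, on 4 arrays, 1 per group. Median intensity was 5.79 in WT vehicle, 5.73 in WT STZ, 5.83 in KO vehicle and 5.96 in KO STZ. Values reached 10392 at most. Correlations between arrays across clusters lay between 0.987 and 0.991, and genes are not independent replicates. No difference below has a replicate check. Higher and lower therefore describe single arrays.

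Klf15, a zinc-finger transcription factor of the Kruppel-like family, was read by 1 cluster. Its intensity was 50.5 in WT vehicle, 72.1 in WT STZ, 19.8 in KO vehicle and 16.04 in KO STZ. The KO arrays stood at 39.3% of WT under vehicle and 22.2% under STZ. The log2 difference between genotypes was -1.20 under vehicle and -1.94 under STZ. STZ differed from vehicle by 0.48 in WT and -0.25 in KO. Whether the cluster lies inside the deleted part of the gene is not given in the sources used here.

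The first comparison asked what loss of KLF15 changed in muscle without diabetes. Genes that break down branched-chain and other amino acids were lower in KO, and collagen genes were higher. Adhfe1, a mitochondrial hydroxyacid dehydrogenase, showed the largest decrease, at -2.60 on the log2 scale, from an intensity of 102.4 to 13.8. Aldh6a1, which acts in valine breakdown, stood at -1.49, and Gstk1, a glutathione transferase, at -1.38. In all, 3 genes were at least 2-fold higher and 10 at least 2-fold lower among 13258.

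Of 24 measured genes of amino acid catabolism, 7 were at least 1.5-fold lower in KO vehicle, 0 were 1.5-fold higher and 17 lay between. The list median was -0.37, at percentile 0 of random lists. Bckdhb, a subunit of the branched-chain keto acid dehydrogenase, stood at -0.998, Ivd, of leucine breakdown, at -0.91 and Aldh4a1, of proline breakdown, at -0.81. Bcat2, the mitochondrial branched-chain aminotransferase, stood at -0.64 and Prodh, the proline dehydrogenase, at -0.053. All 17 measured extracellular matrix genes were above 0, with 4 at least 1.5-fold higher and a median of 0.47, at percentile 100. Col1a1 stood at 0.76, Col1a2 at 0.68, Col3a1 at 0.64 and Sparc at 0.60. Markers of tendon (median 0.38), fibroblasts (0.23), endothelium (0.21) and adipocytes (0.19) were apart on the same side. Small nucleolar RNAs had a median of 0.10 and ribosomal proteins one of -0.082, at percentiles 100 and 0.95. Here and below, both classes were picked by gene symbol. The ribosomal protein class can therefore take in kinase genes whose symbols also begin with Rps.

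Slow fibre genes had a median of -0.26 in KO vehicle against WT vehicle, with Tpm3 at -0.52 and Tnni1, the slow troponin I, at -0.49. Immediate early genes had a median of -0.18, with Fos at -0.86 and Egr1 at -0.79 but Nr4a3 at 0.91. The other KLF factors had a median of -0.15. The glucocorticoid-responsive list (median 0.071) and oxidative phosphorylation (median -0.0018) sat at the upper threshold and were called in 3 of 6 random draws each. The former lost its call in 7 of 7 alternatives and the latter in 2 of 7, with a change of sign in 3 others, so no direction is drawn from them. Among single genes, Pck1, which encodes a gluconeogenic enzyme also active in fat cells, stood at 1.14, Thbs1 at 1.01, Chad at 0.99 and Nupr1 at 0.98. Ormdl2 stood at -1.30, Ostn, which encodes the muscle-secreted peptide musclin, at -1.12, Pxmp2, a peroxisomal membrane protein, at -1.05 and Wnt4 at -1.04. The atrophy ubiquitin ligases and regulators had a median of -0.0097 at percentile 65.7, which turned positive under quantile normalization and loess, with Trim63, a muscle ubiquitin ligase, at 0.38 and Fbxo32, another, at -0.032. Lists that were not apart had medians from -0.16 to 0.15. Close to the limits were macrophage markers (0.15, percentile 96.9), smooth muscle markers (0.12, percentile 96.8) and polyamine metabolism (-0.16, percentile 2.99). They were called in 2, 3 and 1 of 7 alternatives, in that order.

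**Figure D1:**
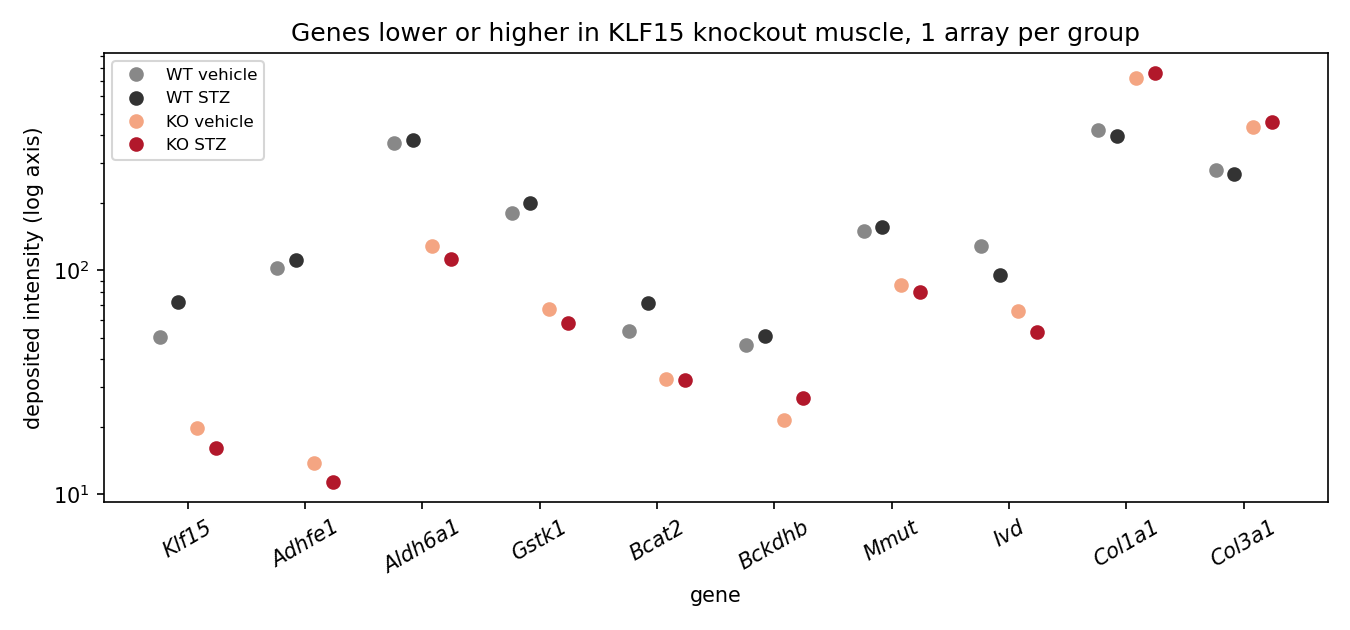
Deposited intensity on a log axis for 10 genes, with 1 point per array and colour for the group. Klf15 and the 7 genes to its right are lower on both KO arrays than on both WT arrays (Aldh6a1 at 368 and 381 in WT, 129 and 112 in KO), while Col1a1 and Col3a1 are higher; the points are single arrays with no error.

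The second comparison asked what loss of KLF15 changed in STZ-treated muscle. The same amino acid and matrix lists stood apart, and fatty acid oxidation, slow fibre and immediate early genes were lower in KO. In all, 7 genes were at least 2-fold higher and 38 at least 2-fold lower. These counts were 9 and 26 under quantile normalization and 8 and 29 under loess. Genes above level percentile 75 had a median of -0.11 in this comparison. Bright genes as a whole therefore sat lower on the KO STZ array than on the WT STZ array. Against vehicle, these genes had medians of 0.035 in WT STZ and -0.063 in KO STZ, so the shift does not belong to the KO STZ array alone. Their median was -0.098 for the difference between STZ effects. Adhfe1 stood at -2.93, Egr1, an activity-induced transcription factor, at -2.15, Snord58b, a small nucleolar RNA, at -1.76, Aldh6a1 at -1.74, Gstk1 at -1.71 and Rps13, a ribosomal protein, at -1.32. Small nucleolar RNAs had a median of -0.30 over 60 genes and ribosomal proteins one of -0.21 over 74, both at percentile 0. Amino acid catabolism had a median of -0.38 over 24 genes, of which 7 were at least 1.5-fold lower and 0 higher, and the median was -0.20 under quantile normalization. Bcat2 stood at -1.06, Mmut, the methylmalonyl-CoA mutase, at -0.94 and Mccc2 at -0.85.

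Of 28 fatty acid oxidation genes, 9 were at least 1.5-fold lower in KO STZ than in WT STZ, 0 were higher, and the median was -0.38. Acot2, a mitochondrial acyl-CoA thioesterase with close copies that share probes, stood at -1.38, Acadl at -0.84, Plin5 at -0.83 and Mlycd at -0.75. Adipocyte markers were lower as well, with a median of -0.42. Slow fibre genes had a median of -0.49 (-0.31 under quantile normalization), with Tnni1 at -1.32 and Tnnc1 at -1.04. Immediate early genes had a median of -0.42 and 7 of 21 at least 1.5-fold lower, among them Btg2 at -0.97 and Klf4 at -0.96. Hspa1b, an inducible chaperone whose near-identical copy can share its probes, stood at -1.72. Extracellular matrix genes had a median of 0.46, and 7 of 17 were at least 1.5-fold higher. Col1a1 stood at 0.92, Col3a1 at 0.76, Col1a2 at 0.75 and Col5a2 at 0.67. Tendon (median 0.30, from 0.18 to 0.43 over 7 alternatives) and macrophage (0.19) markers were apart on the higher side. Fibroblast markers were called apart with a median of 0.056 and 5 of 10 genes below 0, a call that ended under quantile normalization (percentile 94.3) and loess (93.7). The atrophy list had a median of -0.12 at percentile 50.0, which turned positive under quantile normalization and loess, with Fbxo32 at -0.70 and Trim63 at -0.21, the latter 0.0062 under quantile normalization. Glycolysis and glycogen genes were called apart with a median of -0.037, which turned to 0.11 and lost the call under quantile normalization and turned to 0.16 with the call kept under loess, so no direction is drawn.

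Of the genes at least 2-fold lower in KO, Adhfe1, Aldh6a1, Gstk1 and Klf15 were so under both treatments, where independent lists of 10 and 38 genes would share 0.029. At 1.5-fold, 32 genes were shared on the lower side (2.89 if independent) and 8 on the higher side (0.65 if independent). The latter were Col1a1, Col1a2, Col3a1, Mir187, Mir188, Snord88c, Sox4 and Vmn1r20, of which Mir187 and Sox4 are named outside the rule. The values for independent lists take every gene as equally likely to be called, which did not hold. Of chemosensory receptor genes, 5.1% passed 1.5-fold under vehicle and 15.2% under STZ, against 1.36% and 3.65% of all genes. Across 13258 genes the KO differences under vehicle and under STZ correlated with r = 0.23 (rho = 0.19).

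The third comparison asked what STZ changed in WT muscle. Fatty acid oxidation, interferon, immediate early, glucocorticoid-responsive and antioxidant genes were higher, and insulin signalling genes were lower. In all, 13 genes were at least 2-fold higher and 3 at least 2-fold lower. Apold1, an endothelial early response gene, stood at 1.65, Bcl6b at 1.25 and Mss51, a muscle mitochondrial protein, at 1.18. Snord58b (1.46), Snora15 (1.15), Snord1b (1.06) and Rps13 (1.11) belong to small nucleolar RNA and ribosomal protein families, which were higher as classes on this array. Small nucleolar RNAs had a median of 0.38 over 60 genes and ribosomal proteins a median of 0.21 over 74. On the lower side were Gm4841 at -1.11, Dhrsx at -1.04 and F830016B08Rik at -1.004, of which the first and last are interferon-inducible GTPases with close copies. Fasn, the fatty acid synthase, stood at -0.84.

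Of 28 fatty acid oxidation genes, 22 were above 0 in WT STZ and 3 at least 1.5-fold higher, with a median of 0.18. Acot2 stood at 0.76, Slc25a20, the carnitine carrier, at 0.64 and Acadl at 0.61. Interferon and antigen presentation genes had a median of 0.22, with Ifit1 at 0.83 and Gbp3 at 0.72. Immediate early genes had a median of 0.20, with 5 of 21 at least 1.5-fold higher, led by Egr1 at 0.95. Glucocorticoid-responsive genes had a median of 0.19, with Mt2 at 0.76 and Errfi1 at 0.73. The antioxidant list, which also holds metallothionein genes, had a median of 0.18, with Nqo1 at 0.66. The insulin signalling and growth list had a median of -0.11, with Igf1 at -0.53. Over 7 alternatives these medians stayed apart, ranging from 0.11 to 0.19 for antioxidant, 0.18 to 0.33 for immediate early and -0.18 to -0.11 for insulin signalling genes, and up to 0.33 for interferon genes. Glycolysis and glycogen genes had a median of -0.081, at percentile 1.03, a call that ended under quantile normalization and with the mean of all clusters of a gene (-0.066).

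The atrophy ubiquitin ligases and regulators were not apart in WT STZ, with a median of 0.10 at percentile 93.0. That median was 0.030 under quantile normalization and 0.055 under loess. Of 23 genes, 1, Cebpd at 0.69, was at least 1.5-fold higher. Fbxo32 (atrogin-1) stood at 0.36 and Trim63 (MuRF1) at 0.40, while Foxo3 was at -0.064, Cebpb at 0.13 and Wwp1 at -0.041. Il6 and Tdo2 lay below the level filter. Amino acid catabolism had a median of 0.020, which turned negative under quantile normalization and loess, and Bcat2 stood at 0.40. Medians of the other lists that were not apart were 0.088 for proteasome, 0.076 for autophagy, 0.076 for oxidative phosphorylation and -0.060 for lipid synthesis. Their lowest values over 7 alternatives were, in that order, 0.019, 0.022, 0.0035 and -0.10. Further medians were -0.035 for fast fibre genes, 0.036 for denervation genes, -0.059 for polyamine metabolism and -0.059 for extracellular matrix. The denervation median turned to -0.040 without a level filter and -0.12 with the filter at percentile 75, where polyamine metabolism stood at 0.0021. Slow fibre genes (0.049), the circadian clock (0.019) and the heat shock list (0.048) had medians that changed sign under quantile normalization, and the other KLF factors stood at 0.045. Cell markers had medians of 0.18 for macrophages, 0.17 for endothelium, 0.10 for fibroblasts, 0.11 for smooth muscle, 0.20 for tendon, 0.090 for adipocytes and -0.012 for satellite cells. None was called apart, but macrophage markers, at percentile 97.04, were called in 5 of 7 alternatives.

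The fourth comparison asked what STZ changed in muscle lacking KLF15. Interferon genes were higher, and fatty acid oxidation, adipocyte and slow fibre genes were lower. In all, 5 genes were at least 2-fold higher and 6 at least 2-fold lower. Iigp1, an interferon-inducible GTPase with close copies, stood at 1.01. Vmn1r103 (1.22) and Vmn1r20 (1.10) are vomeronasal receptor genes read at intensities of 17.9 and 19.0 on the KO STZ array, in a family whose median intensity was 3.19. Scd1, the stearoyl-CoA desaturase, stood at -1.47, Nmrk2, a muscle kinase of NAD synthesis, at -1.46, Hspa1b at -1.45, Fasn at -1.06 and Nr4a3 at -1.04.

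Interferon and antigen presentation genes had a median of 0.30 in KO STZ, with 5 of 19 at least 1.5-fold higher, among them Ifit2 at 0.83, Gbp3 at 0.72, Tap1 at 0.69 and Ifit1 at 0.69. Glucocorticoid-responsive genes had a median of 0.12 and macrophage markers one of 0.19. Small nucleolar RNAs (0.0064, percentile 99.2) and ribosomal proteins (0.049, percentile 100) lay outside the random range as well. Fatty acid oxidation genes had a median of -0.18, with 22 of 28 below 0, Ppargc1a at -0.69 and Acot2 at -0.54. The median shrank to -0.092 under quantile normalization and to -0.11 under loess, still called apart. Adipocyte markers had a median of -0.53, with Retn at -0.75 and Plin1 at -0.64. Slow fibre genes (-0.21) and endothelial markers (-0.23) were also lower. Smooth muscle markers were called apart at -0.21, a call that ended under quantile normalization (-0.14), loess (-0.15) and the level filter at percentile 75. Lipid and cholesterol synthesis genes, the list of Scd1 and Fasn, were not called apart at a median of -0.15 (percentile 2.97), but were in 5 of 7 alternatives. The atrophy list had a median of -0.095 at percentile 25.4, with Fbxo32 at -0.31 and Trim63 at -0.19, and amino acid catabolism one of -0.11. Under quantile normalization these 2 list medians were -0.027 and -0.047. With the mean of all clusters of a gene the atrophy median was -0.042, at percentile 69.8.

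**Figure D2:**
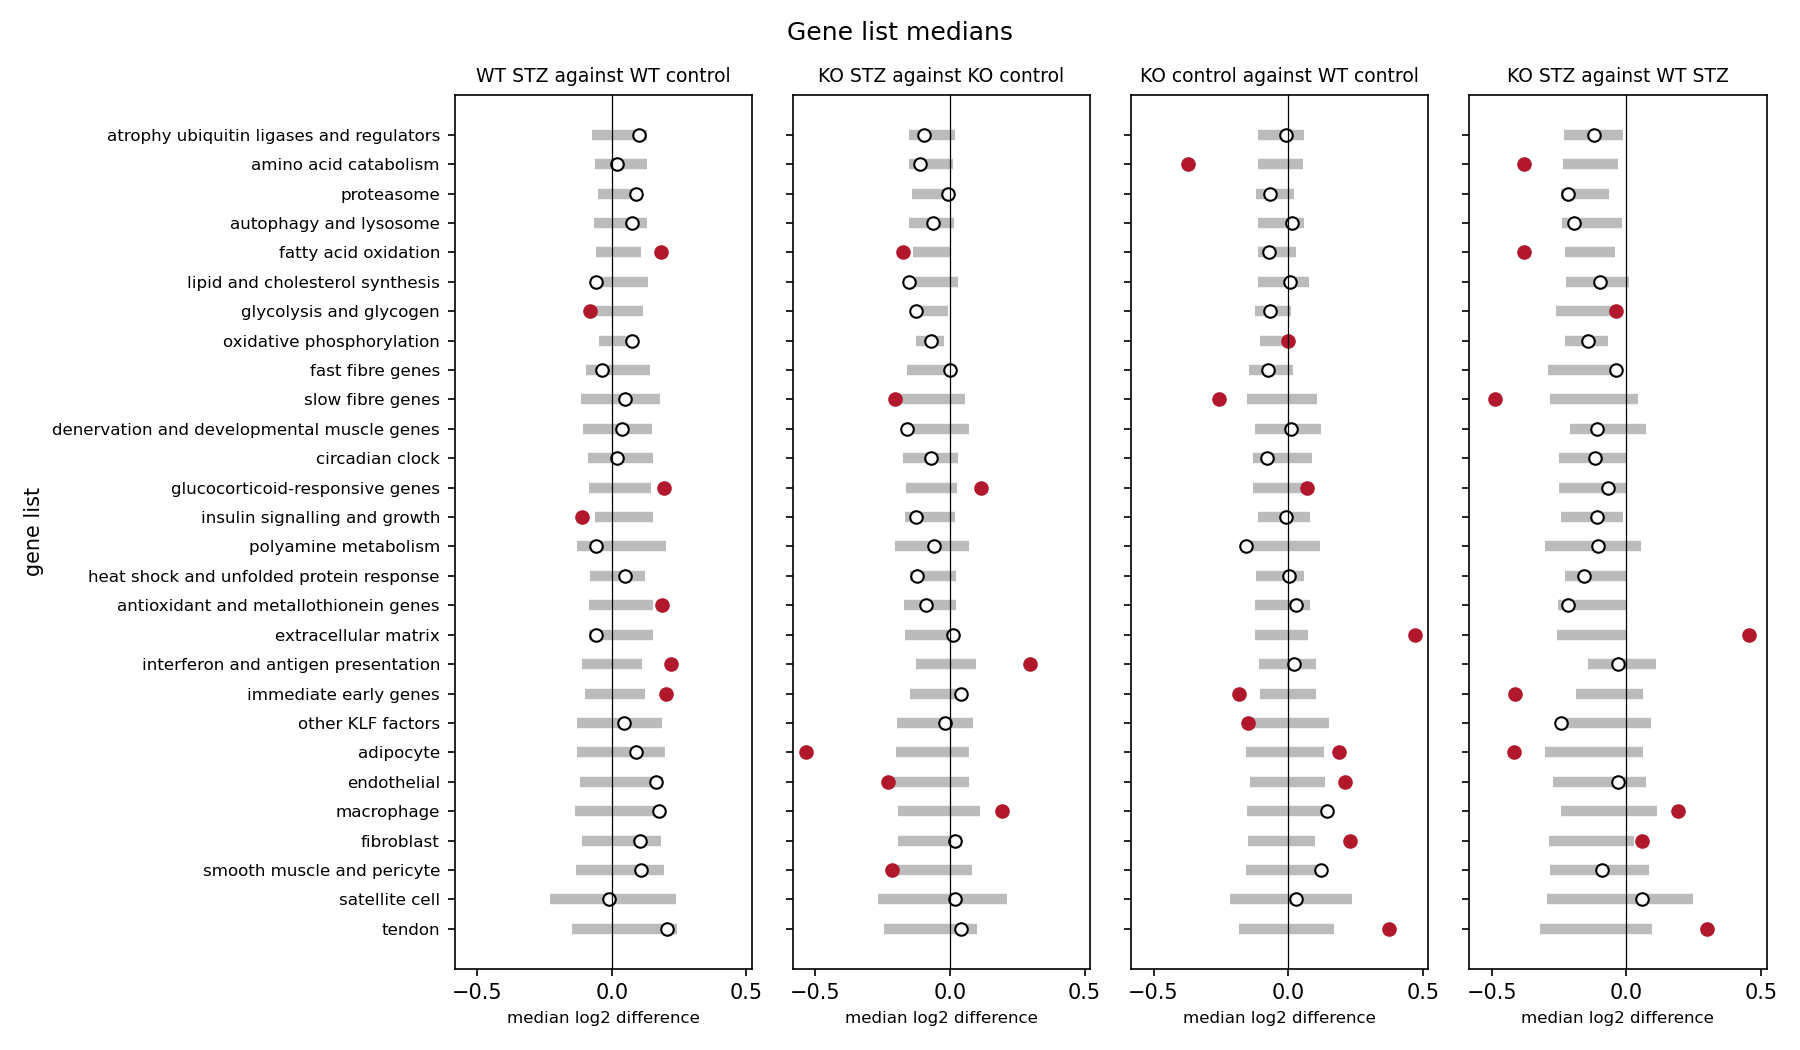
Median log2 difference of each of 28 gene lists in the pairwise comparisons, with grey bars for the range of 10000 random lists of like level inside which a list was not called. Filled points were called apart, among them amino acid catabolism at -0.37 and -0.38 and extracellular matrix at 0.47 and 0.46 in the KO against WT panels.

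The last comparison asked whether the STZ effect differed between genotypes. The log2 STZ effect in KO minus that in WT was at least 1 in 18 genes and at most -1 in 33. Hspa1b stood at -1.995, Snord58b at -1.87, Nr4a3 at -1.84, Apold1 at -1.65, Rps13 at -1.52, Fhl5 at -1.43 and Egr1 at -1.36, and Rab3c stood at 1.44. Small nucleolar RNAs had a median of -0.41 and ribosomal proteins one of -0.18 in this comparison, which uses the WT STZ array as well. Fatty acid oxidation genes had a median of -0.31, with 27 of 28 below 0, Acot2 at -1.30 and Cd36 at -0.88. That median ranged from -0.38 to -0.19 over 7 alternatives. Adipocyte markers stood apart on the same side at -0.64, as did antioxidant genes (-0.36, and -0.20 under quantile normalization), endothelial markers (-0.41) and slow fibre genes (-0.29). The slow fibre call ended under loess (-0.18) and with the level filter at percentile 75 (-0.30). Fast fibre genes were apart at 0.049, a call that ended under quantile normalization. Extracellular matrix genes (0.019, percentile 96.7) were not called, but were in 4 of 7 alternatives. Smooth muscle markers (-0.28) were called in 2 of 7 alternatives only. Immediate early genes (-0.13) were called in 1 of 7, with medians down to -0.47. Fbxo32 stood at -0.67 and Trim63 at -0.59, but the atrophy list as a whole had a median of -0.10 at percentile 43.8. The atrophy median was -0.019 under quantile normalization and -0.039 under loess. Amino acid catabolism had a median of -0.083, which turned positive under quantile normalization and loess.

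Iigp1 alone was at least 2-fold changed by STZ the same way in both genotypes, where independent lists would share 0.0049 genes. Its log2 differences were 1.04 and 1.01, close to the threshold: 0 genes were shared under quantile normalization, and 3 with a floor or nothing in place of the offset. At 1.5-fold, 8 genes were higher in both (0.75 if independent) and 3 were lower in both (0.39 if independent). The latter were Fasn, Scd1 and Kcng4, a potassium channel subunit. The former were Gbp3, Ifit1, H2-Q4, Iigp1, Rps23, the pseudogene Gm16519 and the vomeronasal receptor genes Vmn1r103 and Vmn1r127, the last named outside the rule. The values for independent lists take every gene as equally likely to be called, which did not hold. Of chemosensory receptor genes, 6.3% passed 1.5-fold with STZ in WT and 10.1% in KO, against 1.72% and 1.10% of all genes. An excess over those values is therefore not evidence of a shared STZ response. The STZ effects of the genotypes correlated across 13258 genes with r = 0.056 (rho = 0.046).

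**Figure D3:**
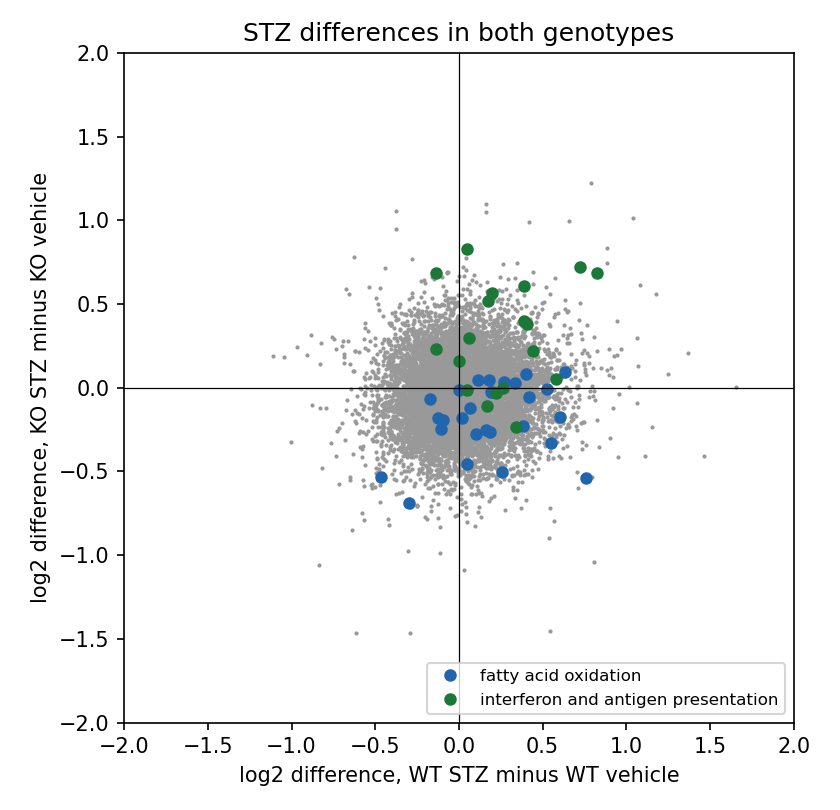
Log2 difference of STZ against vehicle for each of 13258 genes, WT on the horizontal and KO on the vertical axis, with fatty acid oxidation genes in blue and interferon genes in green. Oxidation genes have medians of 0.18 in WT and -0.18 in KO, and interferon genes of 0.22 and 0.30; points are single-array differences.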

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

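Except for the test of small nucleolar and ribosomal protein transcripts, the tests in this part were chosen after the result was seen. That test concerns classes with members among the largest WT STZ increases, and the class medians include those members. None of the differences between genotypes or treatments named here was tested.

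The fatty acid oxidation list moved in opposite directions with STZ, higher in WT and lower in KO, with a median difference between the effects of -0.31. Less fat tissue in the KO STZ sample can bear only on the part that involves that array, not on the WT STZ median of 0.18, where adipocyte markers were not apart (0.090, percentile 76.2). For the KO part it stays open. Adipocyte markers stood at -0.64 in the same comparison, and 6 of them at -0.57 against KO vehicle and -0.45 against WT STZ. The fall of the oxidation genes against WT STZ minus that against KO vehicle, a median of -0.25, leaves out the KO STZ array and decides nothing. Against KO vehicle, 2 muscle-typical genes, Ucp3 (-0.45) and Fabp3 (-0.19), with a median of -0.32, were too few to decide. A trend of the log2 difference with level is argued against as the whole cause of the fall in KO STZ against WT STZ. That test was not made for the STZ effects within each genotype. The median difference between those effects ranged from -0.38 to -0.19 over 7 alternatives. The bound for the list median was set with its value known. Only the upper quartile, required to lie below 0, was not known beforehand. After removal of the loess trend the list median of KO STZ against WT STZ went from -0.38 to -0.26, with an upper quartile of -0.053 and 23 of 28 genes below 0, so part of the difference moved with that trend. Slow fibre genes were also lower on the KO STZ array, at -0.21 against KO vehicle and -0.49 against WT STZ. The WT STZ array, taken up in the next paragraph, enters the pattern as well. Whether either bears on the oxidation genes was not tested. Loss of KLF15 itself, the design's biological explanation, was not tested.

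Small nucleolar and ribosomal protein transcripts were among the largest WT STZ increases. Both families were higher as classes, with medians of 0.38 and 0.21, which is consistent with a difference in RNA quality or labelling of the WT STZ array. An effect of diabetes on ribosome production would give the same values and was not tested apart from it. The same array enters KO STZ against WT STZ, where the class medians were -0.30 and -0.21, and the difference between STZ effects, where they were -0.41 and -0.18. The classes also left the random range without that array, by less: 0.10 and -0.082 in KO against WT under vehicle, and 0.0064 and 0.049 for STZ in KO.

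Extracellular matrix genes were higher in KO under both treatments. More fibroblasts in the KO samples are argued against as the whole cause under STZ. There, 8 non-collagen fibroblast markers had a median of -0.016, below the lower quartile of 0.45 of the 11 collagen genes. Under vehicle their median of 0.22 was also below that quartile, but close to it (0.27). The fibroblast list was itself apart under vehicle at 0.23 (percentile 99.98), so a contribution of fibroblasts there stays open. More tendon cannot be told apart from a change in the muscle. The 7 tendon markers stood at 0.30 under STZ, below the lower collagen quartile, but at 0.38 under vehicle, between the collagen quartiles. Dissection of the muscle at its tendon could therefore contribute, and an effect of KLF15 loss on collagen genes stays open.

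Adipocyte markers were higher in KO than WT under vehicle and lower under STZ, a difference of -0.64. Fut11 was lower with STZ in WT and higher in KO, a difference of 1.27. Nr4a3 was higher with STZ in WT and lower in KO, and likewise higher in KO under vehicle and lower under STZ, a difference of -1.84. Zfp108 went the opposite way in both readings, a difference of 1.41. Svop was lower in KO under vehicle and higher under STZ, a difference of 1.32. Among 6743 clusters above the level filter that carry no single gene symbol and enter no comparison, 193 differed at least 2-fold between WT STZ and WT vehicle, 209 between KO STZ and KO vehicle, 182 between KO and WT under vehicle and 358 under STZ.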

How the results depend on the processing

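No paired analysis was possible because each group holds 1 array and the labels give no replicate numbers, and no array could be left out for the same reason. The alternative without probe sets shared between genes was not run, because cluster names on this array carry no such marks. Over all alternatives, 69 of the recomputed gene counts stayed within 1.5 times and 41 did not. Of list medians, 856 kept their direction and side of the threshold, 61 that were not apart changed sign, 29 gained the call, 19 lost it and 10 changed sign while called in at least 1 of the compared settings. For named genes the unit was 1 gene in 1 comparison under 1 alternative. Of these results, 4821 kept direction and side of 1.5-fold, 95 passed it, 48 dropped below it and 27 small differences changed sign. The 4821 include 735 without a level filter and 581 with the filter at percentile 75, which could not change, because a filter leaves a gene's difference as it is. Genes that the stricter filter removed were not counted there. The lower amino acid catabolism in KO stayed at or below percentile 0.02 under each of 7 alternatives, with medians from -0.39 to -0.26 under vehicle and from -0.40 to -0.20 under STZ. Extracellular matrix stayed at percentile 100 in both. A change of random draw also moved the call of the proteasome in KO STZ against KO vehicle (called in 1 of 6 draws) and of oxidative phosphorylation and the glucocorticoid-responsive list in KO against WT under vehicle (3 of 6 each). Processing moved them too: the glucocorticoid-responsive list lost its call in 7 of 7 alternatives and oxidative phosphorylation in 2 of 7, while the proteasome gained it in 3 of 7.

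Counts of 2-fold genes follow as higher and lower. With a floor in place of the offset they were 27 and 10 for STZ in WT, 13 and 17 for STZ in KO, 12 and 27 for KO under vehicle, 24 and 72 for KO under STZ, and 74 and 108 for the difference between STZ effects, with 3 shared STZ calls. With no offset they were 27 and 10, 13 and 17, 13 and 27, 24 and 72, and 74 and 108, with 3 shared. Both settings remove the damping of dim genes that the offset gives by construction. At 1.5-fold they were 169 and 59, 59 and 87, 77 and 103, 112 and 372, and 233 and 519, with 11 shared, a looser threshold by construction. With the level filter at percentile 75, fewer genes enter, and the counts that moved were 3 higher for STZ in KO, 4 higher for KO under STZ, and 6 and 21 for the difference between STZ effects. With protein-coding genes without receptors, an alternative chosen after seeing the data, 7 were higher for STZ in WT, 3 higher for STZ in KO and 2 higher for KO under STZ. Under quantile normalization 0 STZ calls were shared, and the cause was not tested.

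The atrophy list median turned to 0.033 (quantile) and 0.026 (loess) for KO under vehicle and to 0.057 and 0.028 for KO under STZ. Amino acid catabolism turned to -0.058 (quantile) and -0.028 (loess) for STZ in WT and to 0.047 and 0.019 for the difference between STZ effects. None of these was apart in either setting. Medians that changed sign while called were the proteasome for STZ in KO, at 0.065 (quantile), 0.059 (loess) and 0.0044 (mean of clusters), oxidative phosphorylation for KO under vehicle, at 0.055 (quantile), 0.073 (loess) and 0.0041 (mean of clusters), glycolysis for KO under STZ, at 0.11 (quantile) and 0.16 (loess), fast fibre genes for KO under STZ at 0.17 (loess), and interferon genes for KO under STZ at 0.13 (level filter at percentile 75). The causes were not tested. Dim genes limit the reading of single differences. Of 79 chemosensory receptor genes above the filter, 15.2% passed 1.5-fold between KO STZ and WT STZ, against 3.65% of all genes. Clusters of the same gene differed by a median SD of 0.15 in that comparison. The receptor genes also had a median of 0.14 there, at percentile 100, and microRNAs one of 0.085, at percentile 99.99. Classes outside the fixed lists can therefore reach such percentiles too, and a call alone does not show a change particular to a pathway.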

Other observations

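The genes in this paragraph were chosen after their values were seen. Of the 32 genes lower on both KO arrays by at least 1.5-fold, 4 outside the amino acid list are given here, as single genes. Pfkfb3, which sets the level of a glycolysis activator, stood at -0.94 under vehicle and -0.89 under STZ. Aldh2, a mitochondrial aldehyde dehydrogenase, stood at -0.82 and -1.13, Kyat3, a kynurenine aminotransferase, at -0.65 and -0.73, and Micu3, a regulator of mitochondrial calcium uptake, at -0.73 and -0.83. Gm4841 had an intensity of 155.5 in WT vehicle against 70.1 in WT STZ and 50.6 in KO vehicle, so that array stood apart from the other arrays for this gene.

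Marker lists with fewer than 5 measured genes were given no percentile. In KO against WT under vehicle, Ighm of the lymphocyte list stood at -0.80, Slc4a1 of the red cell list at -0.18 and Krt10 of the epidermis list at 0.36. The median was 0.082 over 3 brown adipocyte genes, -0.12 over 3 Schwann cell genes and 0.091 over 3 sex-linked genes. Of the neutrophil list 0 genes passed the level filter.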
